A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

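Polyadenylated RNA of 4 samples of the industrial Saccharomyces cerevisiae strain CY was sequenced after 10 h of growth, 2 libraries from non-stress cultures grown at 30 °C in 2% glucose and 2 from stress cultures grown at 36 °C in 10% glucose. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was taken with oligo(dT) beads, and complementary DNA primed with random hexamers was circularized and sequenced as DNA nanoballs. Libraries were grouped by the condition given in the labels.

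The authors deposited 1 table with an FPKM value per gene and library, rounded to 2 decimals, as named in the file headers and sample descriptions. FPKM divides the fragments of a gene by its length and by the mapped fragments of the library. The submitters' processing notes list HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8 and the genome build R64, with no role or order, and any filter on reads is not given in the sources used here. RSEM is known to share reads that fit several genes between them by an estimate, so values of near-identical genes are uncertain. Another deposited column gives the length of each gene's longest transcript; 98.8% of these lengths are multiples of 3, so they are coding lengths without untranslated regions. The FPKM sums of the libraries were 988848 and 1009867 (non-stress) and 1058448 and 1064993 (stress). FPKM is a share of each library, and a fall in very abundant transcripts raises the values of all others.

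Of the 5897 genes in the table, 5894 were matched by gene identifier to the R64 reference annotation, all as protein-coding genes, and 5814 had identical coordinates in both. Of the coding genes of the reference, 127 were not in the table and were not analysed here. Coordinates are 1-based. For 5894 genes, the percent of 50-base windows that also occur in another coding sequence was computed. More than 50% of windows were shared for 194 genes, and 35 genes had values identical to those of another gene in all 4 libraries. In all libraries 39 genes were listed at 0.

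Depth was estimated from low values: FPKM values worth under 8 reads were tested for being whole multiples of what 1 read is worth for a gene of that length, and the depth and length offset that gave the clearest steps were taken. Between 98.1% and 100% of the low values (52 to 76 in each library) lay within 0.1 of a whole number, against 20% by chance before this choice. The estimates were 18500000 and 18600000 fragments (non-stress) and 17800000 and 18000000 (stress), with gene lengths shortened by 35 or 36 bases. These are estimates, and tests that need read counts were not run. Replicates were compared on estimated reads. The median chi-square per gene was 2.01 in non-stress and 0.78 in stress libraries, where sampling alone gives 0.45, so no pair was treated as a single library.

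The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), comparing stress with non-stress on log2(FPKM + 1), a pseudocount of 1. Genes with an FPKM of at least 1 in at least 2 libraries were kept, which removed 113 and left 5784. The test was two-sided with 2 residual and 6.51 prior degrees of freedom, Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, while plain folds are ratios of mean FPKM. The median standard error of a log2 fold change was 0.07.

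Gene lists, tests and alternatives were fixed before the data were examined, except where stated. The 35 lists were tested with limma's camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. PHO12 of the phosphate list was not in the table and was not analysed here. The naming rule took the 8 largest rises and the 8 largest falls among genes past the threshold with separated groups and a mean FPKM of at least 20. It took up to 3 members of each list with the largest change at that mean level, and 16 genes named in any case. Together these were 117 genes. Alternatives were quantile normalization, no filter, a minimum FPKM of 5, a pseudocount of 0.1, the replicate number as a block, each library left out in turn and a threshold of 0.01. Rescaling all libraries to the same FPKM sum, median centring and leaving out genes with over 50% shared windows were added after the data were seen.

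For the closing section, gene ontology terms of 15 to 80 tested members, taken from the deposited table, were tested with camera. Pairs of duplicate genes were reciprocal best protein matches (BLAST 2.17.0) with at least 50% identity over at least 80% of the longer protein. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.

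The limma and camera steps were tested on simulated data: 5784 genes with the non-stress means, the real replicate spread and sampling noise, of which 220 were changed, 200 in the 4 fold classes below and 20 in a raised list. With 2 libraries in each group, 26% of genes changed 1.25-fold and 76% of those changed 1.5-fold were recovered. Of those changed 2-fold and 4-fold, 96% and 100% were recovered. Of 172 calls, 17 of them in the raised list, 3.5% were false. The raised list was found, and 0 of 30 unchanged lists were called. The simulation changed far fewer genes than were called in the data and held no shift in library composition. Its shares therefore need not hold for the real comparison.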

Results

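RNA was sequenced from an industrial strain of budding yeast, Saccharomyces cerevisiae CY, after 10 h of shaken growth in rich medium made with yeast extract, peptone and glucose. There were 2 groups of 2 libraries. The non-stress libraries came from cultures at 30 °C with 2% glucose, and the stress libraries from cultures at 36 °C with 10% glucose. Each library was described by an FPKM value (fragments scaled by the length of the transcript and by the mapped fragments of the library) for each of 5897 genes. Depth, estimated from the steps between low FPKM values, was 18500000 and 18600000 fragments for the non-stress libraries and 17800000 and 18000000 for the stress libraries. Between 63 and 82 genes were listed at 0 in a library. Replicates had a Pearson r across genes of 0.9965 (non-stress) and 0.9979 (stress) on the log2(FPKM + 1) scale, where genes are not independent replicates. The SD of the log2 difference between replicates was 0.156 and 0.137.

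The comparison of the groups asked how the transcriptome of this strain differed between ordinary growth conditions and heat combined with a high sugar concentration, a setting that the series title ties to tolerance genes and xylose fermentation. In the libraries labelled stress, genes for respiration, gluconeogenesis, use of carbon sources other than glucose, storage carbohydrates and the general stress response were mostly higher, and genes for cytosolic ribosomes, their assembly, glycolysis and the synthesis of arginine, lysine, histidine and branched-chain amino acids were mostly lower. Of 5784 genes tested with limma, 5071 (87.7%) changed at a Benjamini-Hochberg adjusted p threshold of 0.05. Of these, 2300 were higher and 2771 lower under stress. That balance depends on scaling, with 2692 higher and 2381 lower after quantile normalization. After rescaling to equal FPKM sums 2138 were higher and 2933 lower. A change of at least 2-fold was estimated for 2658 genes, 1100 higher and 1558 lower, and a change of at least 8-fold for 214 higher and 342 lower genes. The groups did not overlap for 5424 genes (93.8%), against 33.3% by chance with 2 libraries on each side. The first principal component separated the groups and held 99.3% of the variance. The group means had a Pearson r of 0.624 and a Spearman rho of 0.635 across genes, far below the r between replicates. Temperature and glucose changed together, so their effects could not be separated. Nothing in the labels says that replicates came from separate cultures, and the p-values measure only the spread between these samples, which may be technical.

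**Figure D1:**
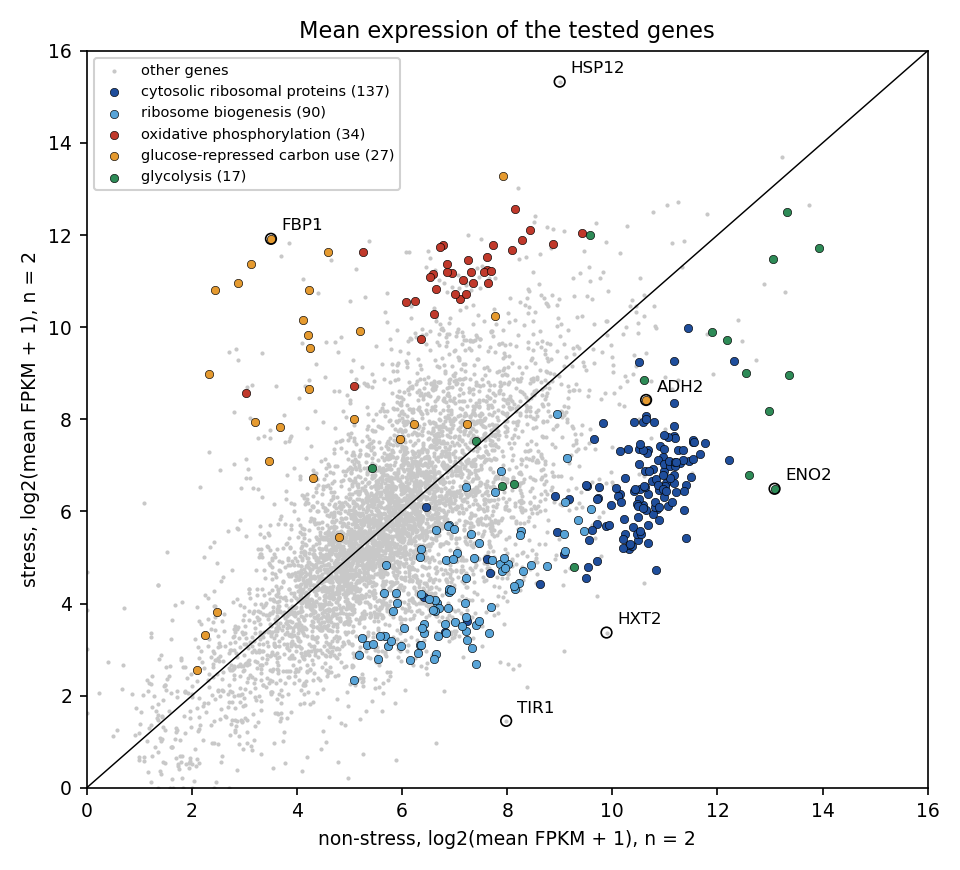
Mean expression of the 5784 tested genes in the 2 stress libraries (vertical axis) against the 2 non-stress libraries (horizontal axis), both as log2(mean FPKM + 1), with the line of equal expression. Coloured points are members of 5 gene lists and open circles mark named genes; all 137 cytosolic ribosomal protein genes lie below the line and all 34 oxidative phosphorylation genes above it.

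The 8 genes with the largest rises were FBP1, SFC1, PCK1, IDP2, DDR2, GRE1, SIP18 and MLS1. FBP1 encodes the gluconeogenic enzyme fructose-1,6-bisphosphatase and lies on chromosome XII at 873746 to 874792 on the minus strand, as a single coding exon in the R64 annotation. It went from 10.4 ± 0.0141 to 3867 ± 75.1 FPKM (SD, n = 2), a 373-fold rise with a log2 fold change of 8.41 ± 0.049 (SE; limma adjusted p = 8.06e-13). SFC1, the mitochondrial succinate-fumarate carrier on chromosome X (609773 to 610741), rose from 4.46 ± 1.46 to 1784 ± 2.68 FPKM. PCK1, phosphoenolpyruvate carboxykinase on chromosome XI (631152 to 632801), rose 344-fold, from 7.73 ± 0.827 to 2658 ± 12.4 FPKM. IDP2, cytosolic isocitrate dehydrogenase on chromosome XII (504591 to 505829), rose from 6.38 ± 0.453 to 1993 ± 48.1 FPKM, and MLS1, malate synthase of the glyoxylate cycle on chromosome XIV (406358 to 408022), from 23.2 ± 0.948 to 3158 ± 87.4 FPKM. The stress-induced genes DDR2, GRE1 and SIP18 rose 274-fold, 254-fold and 248-fold, with log2 fold changes of 7.99 ± 0.051, 7.92 ± 0.047 and 7.84 ± 0.051 (SE).

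The 8 genes with the largest falls were ENO2, TIR1, HXT2, ANB1, GPP1, IMD4, RPS22A and RPS26B. ENO2, the main glycolytic enolase on chromosome VIII (451327 to 452640, plus strand), went from 8694 ± 378 to 89.0 ± 2.19 FPKM (SD, n = 2), a log2 fold change of -6.59 ± 0.054 (SE; limma adjusted p = 2.37e-12). Of its 50-base windows, 23.6% also occur in another coding sequence, mainly ENO1. TIR1, a cell wall mannoprotein of anaerobic cells on chromosome V (175248 to 176012), went from 251 ± 42.1 to 1.74 ± 0.0990 FPKM. ANB1, the hypoxic form of translation factor eIF5A on chromosome X (524908 to 525381), went from 332 ± 30.8 to 3.53 ± 1.05 FPKM. HXT2, a glucose transporter on chromosome XIII (288079 to 289704), was 101-fold lower, at 947 ± 167 against 9.35 ± 1.04 FPKM. GPP1, a glycerol-3-phosphatase on chromosome IX (255115 to 255867), was 74.3-fold lower, and IMD4, inosine monophosphate dehydrogenase on chromosome XIII (162194 to 164176), 79.0-fold lower. The small ribosomal subunit genes RPS22A and RPS26B had log2 fold changes of -6.10 ± 0.070 and -6.00 ± 0.090 (SE).

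**Figure D2:**
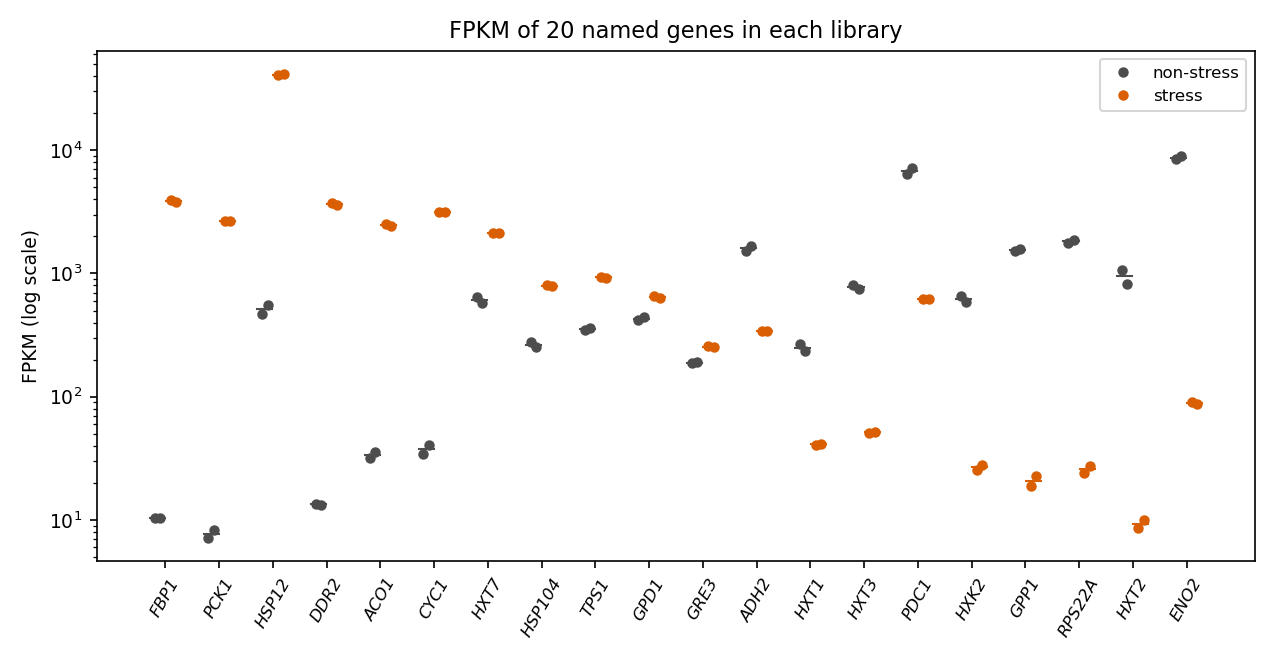
FPKM (vertical axis, log scale) of 20 genes named in the text in each of the 2 non-stress (grey) and 2 stress (orange) libraries; each point is a library and each short line the group mean. The replicates of a group lie close together beside the distance between groups, as for FBP1 (10.4 against 3867) and ENO2 (8694 against 89.0).

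Of 35 gene lists, 23 passed limma's camera test at an adjusted p of 0.05 with its preset correlation of 0.01 between genes, 15 of them up and 8 down. With a correlation estimated for each list from 2 residual degrees of freedom, which leaves little power, 0 passed. The adjusted p of each is given beside its count. For 32 lists, counts of changed members adjusted over the list alone were the same as those over all genes tested. The exceptions were the cell wall, thiamine and hypoxia lists, given below.

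Genes of the cytosolic ribosome and its assembly fell. All 137 cytosolic ribosomal protein genes fell, with a median log2 fold change of -4.11 (camera adjusted p = 7.32e-26; adjusted p = 0.426 with an estimated correlation). Their part of the summed FPKM was 23.1% ± 0.855 in non-stress and 1.55% ± 0.023 in stress libraries (SD, n = 2). RPL11A, of which 60.9% of windows are shared with RPL11B, went from 1629 ± 102 to 39.0 ± 6.35 FPKM. All 90 ribosome biogenesis genes fell, with a median of -2.78 (camera adjusted p = 1.25e-16; adjusted p = 0.426 with an estimated correlation). Among them were the RNA polymerase I subunits RPA43 (-4.71 ± 0.083, SE) and RPA49 (-4.30 ± 0.12) and the ribosomal RNA processing gene RRP1 (-4.30 ± 0.077). In contrast, all 66 mitochondrial ribosomal protein genes rose, with a median of 2.08 (camera adjusted p = 2.17e-18; adjusted p = 0.355 with an estimated correlation), led by MRPL35 (56.1 ± 2.52 to 527 ± 11.2 FPKM), MRPS12 and MRPL49.

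Respiratory genes rose together. All 34 oxidative phosphorylation genes were higher, by a log2 fold change of 2.62 to 6.37 and a median of 3.88 (camera adjusted p = 5.96e-15; adjusted p = 0.355 with an estimated correlation), and their part of the summed FPKM went from 0.58% ± 0.010 to 7.98% ± 0.033 (SD, n = 2). CYC1, cytochrome c, rose 84.7-fold (37.4 ± 4.54 to 3168 ± 17.5 FPKM). NDE2, an external NADH dehydrogenase, and COX12, a cytochrome c oxidase subunit, had log2 fold changes of 5.55 ± 0.065 and 5.01 ± 0.067 (SE). In the tricarboxylic acid cycle list 18 of 21 members rose, with a median of 3.24 (camera adjusted p = 3.32e-06; adjusted p = 0.396 with an estimated correlation). ACO1, aconitase, rose 73.3-fold, and the succinate dehydrogenase genes SDH2 and SDH3 rose 31.4-fold and 21.4-fold. Of 12 mitochondrial chaperone genes 11 rose, with a median of 1.41 (camera adjusted p = 0.000398; adjusted p = 0.355 with an estimated correlation), among them SSC1 (2.30 ± 0.052, SE), HSP60 (2.21 ± 0.057) and HSP10 (2.06 ± 0.049). The exception was MGE1, at -0.13.

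Genes that glucose represses in budding yeast were higher in the libraries labelled 10% glucose. In the list of alternative carbon use and gluconeogenesis 26 of 27 members rose, with a median log2 fold change of 4.42 (camera adjusted p = 3.37e-09; adjusted p = 0.355 with an estimated correlation). The part of the summed FPKM held by this list went from 0.26% ± 0.003 to 3.12% ± 0.034 (SD, n = 2). SUC2, invertase, chosen after its values were seen, was at 240 FPKM in non-stress and 9999 in stress libraries. The exception was ADH2, the alcohol dehydrogenase that consumes ethanol, which fell from 1597 ± 92.8 to 341 ± 1.48 FPKM; 14% of its windows also occur elsewhere, mainly in ADH1. All 15 genes of peroxisomal fatty acid oxidation rose, with a median of 1.73 (camera adjusted p = 4.65e-05; adjusted p = 0.355 with an estimated correlation), including POT1 (34.1-fold), the catalase CTA1 (11.4-fold) and FOX2 (9.22-fold).

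Glycolytic genes fell: 14 of 17, with a median log2 fold change of -1.99 (camera adjusted p = 0.00219; adjusted p = 0.426 with an estimated correlation). Their part of the summed FPKM went from 8.60% ± 0.272 to 1.92% ± 0.064 (SD, n = 2). TDH2, a glyceraldehyde-3-phosphate dehydrogenase with 31.3% of its windows shared mainly with TDH3, was 56.2-fold lower, and CDC19, the main pyruvate kinase, 27.8-fold lower. HXK2, the hexokinase active during growth on glucose, went from 619 ± 51.5 to 26.9 ± 1.69 FPKM. The 2 members that rose, named after their values were seen, were GLK1 (2.44) and PYK2 (1.50), and HXK1 did not pass (0.12). In the ethanol and acetate list 8 of 12 members fell and 3 rose, with a median of -1.85 (camera adjusted p = 0.152). PDC1, the main pyruvate decarboxylase, fell 3.45 ± 0.067 (SE) on the log2 scale, and ALD5 and ADH4 had log2 fold changes of -3.98 ± 0.078 and -3.15 ± 0.057. The 3 that rose were ADH3 (1.53), SFA1 (1.78) and ALD4 (1.43), also named after their values were seen, as was PDC6 (-0.01), which did not pass.

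Genes of hexose transport and glucose sensing went both ways, with 10 of 19 higher and 6 lower (median log2 fold change 0.35, mean -0.24, camera adjusted p = 0.5). The 6 include the glucose sensing genes MTH1 (-1.19) and STD1 (-2.46), named after their values were seen. The low-affinity transporters HXT1 (251 ± 21.5 to 41.2 ± 0.311 FPKM) and HXT3 (782 ± 43.5 to 51.4 ± 1.07 FPKM) fell, with log2 fold changes of -2.58 ± 0.067 and -3.90 ± 0.056 (SE; limma adjusted p = 5.92e-10 and 1.72e-11). HXT5, a transporter of slowly growing cells, rose 12.3-fold, and the high-affinity transporter HXT7 rose from 608 ± 47.4 to 2136 ± 8.66 FPKM. HXT7 shares 95.1% of its windows with HXT6, so the split of reads between them is uncertain; their summed FPKM was 1093 ± 104.5 and 2366 ± 7.60. The 3 that did not pass were HXT9 (-0.15) and HXT11 (-0.08), which share most windows with other genes, and GAL2 (0.20). In the pentose phosphate and endogenous xylose list 9 of 15 members rose and 3 fell, with a median of 0.64 (camera adjusted p = 0.0477; adjusted p = 0.467 with an estimated correlation), and the call was lost without either non-stress library (adjusted p = 0.0912 without replicate 1 and 0.0513 without replicate 2) and under 2 scalings (0.196 after quantile normalization and 0.0645 after median centring). With a minimum FPKM of 5 the median of this list was 1.55, so it depends on the filter. GND2, NQM1 and TKL2, whose closest copies act in the same pathway, rose 49.8-fold, 33.0-fold and 21.7-fold. SOL3 (-1.90), GND1 (-1.90) and TKL1 (-2.97) fell, and RKI1 (-0.08), TAL1 (-0.11) and SOR1 (0.11) did not pass. GRE3, the aldose reductase that reduces xylose, rose 1.35-fold, from 189 ± 3.49 to 255 ± 4.95 FPKM (log2 fold change 0.44 ± 0.050, SE; limma adjusted p = 2.55e-05). A change this small was not tested again with ribosomal protein genes taken out of the total.

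Genes of the general stress response driven by the transcription factors Msn2 and Msn4 rose: 32 of 37, with a median log2 fold change of 3.23 (camera adjusted p = 1.97e-09; adjusted p = 0.355 with an estimated correlation). Their part of the summed FPKM went from 1.05% ± 0.021 to 9.75% ± 0.009 (SD, n = 2). HSP12, a small membrane-associated stress protein gene, rose 80.7-fold, from 510 ± 61.3 to 41165 ± 654 FPKM. CTT1, the cytosolic catalase, rose 5.43-fold (156 ± 1.98 to 847 ± 14.9 FPKM; log2 fold change 2.43 ± 0.048, SE). The 4 that fell, named after their values were seen, were GRE2 (-1.96), GAC1 (-0.91), DDR48 (-0.31) and XBP1 (-0.21), and MSN2 did not pass (-0.06).

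Cytosolic and nuclear heat shock chaperones moved in opposite directions, 15 of 27 higher and 11 lower, with a median log2 fold change of 0.46, a mean of -0.09 and a camera adjusted p of 0.396; STI1 (-0.01) did not pass. HSP26, a small heat shock protein, rose 10.7-fold (434 ± 67.7 to 4637 ± 57.4 FPKM, SD, n = 2), and HSP104, the disaggregase, 3.01-fold (265 ± 17.1 to 797 ± 15.7 FPKM). SSA4, a heat-inducible cytosolic Hsp70, rose 2.27-fold, from 32.4 ± 2.93 to 73.5 ± 0.226 FPKM. The ribosome-associated chaperones SSB1 and SSB2 fell by 4.00 ± 0.059 and 3.63 ± 0.048 (SE) on the log2 scale, with 43.2% of windows shared, and the Hsp110 gene SSE1 fell by 3.56 ± 0.066. In the list of endoplasmic reticulum folding and the unfolded protein response 14 of 19 members fell, with a median of -1.70 (camera adjusted p = 0.0267; adjusted p = 0.426 with an estimated correlation). KAR2, the Hsp70 of this compartment, went from 1033 ± 49.5 to 94.2 ± 2.35 FPKM, and ERO1, a thiol oxidase, and SIL1 were 10.3-fold and 7.03-fold lower. The 5 that rose, named after their values were seen, were EPS1 (1.05), ERV2 (0.86), HRD1 (0.34), CNE1 (0.22) and HRD3 (0.17).

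Most storage carbohydrate genes rose. Of 7 trehalose genes 6 rose, with a median log2 fold change of 1.38 (camera adjusted p = 0.0118; adjusted p = 0.432 with an estimated correlation). Both a synthesis gene, TPS1 (357 ± 8.86 to 929 ± 20.5 FPKM), and the trehalase genes ATH1 (5.30-fold) and NTH1 (3.06-fold) were among them, and TPS3 did not pass (0.01). Of 14 glycogen genes 12 rose, with a median of 1.81 (camera adjusted p = 0.0022; adjusted p = 0.436 with an estimated correlation), including the breakdown genes GDB1 (12.2-fold) and GPH1 (9.24-fold) and the initiator GLG2 (10.4-fold). PGM1 (-2.61) and GAC1 (-0.91) fell. Glycerol and osmotic response genes went both ways, 6 of 18 higher and 12 lower (median -0.54, camera adjusted p = 0.523). GPD1, which makes glycerol-3-phosphate, rose 1.50-fold (429 ± 15.2 to 643 ± 15.2 FPKM), and STL1, a glycerol importer, rose from 4.33 ± 0.354 to 39.6 ± 0.912 FPKM. The glycerol catabolic genes GUT2 and GUT1 rose 31.9-fold and 19.8-fold. Among the 12 that fell were GPD2 (-1.76), the copy of GPD1, and the glycerol-3-phosphatase gene GPP1 (-6.15) with its copy GPP2 (-1.94). GPD2 and GPP2 were named after their values were seen.

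Most protein turnover and redox genes rose, by smaller amounts. Of 36 proteasome genes 24 rose and 4 fell, with a median log2 fold change of 0.33 (camera adjusted p = 0.00304; adjusted p = 0.426 with an estimated correlation), and the call was lost after quantile normalization (adjusted p = 0.381). RPN14, an assembly chaperone of the proteasome, rose 3.09-fold, PUP3 1.83-fold and RPN10 1.79-fold. PRE8 (-0.46), PRE9 (-0.27), RPN1 (-0.25) and PRE2 (-0.19) fell. Of 34 autophagy genes 25 rose and 7 fell, with a median of 1.01 (camera adjusted p = 0.00101; adjusted p = 0.436 with an estimated correlation), led by the mitophagy gene ATG33 (9.95-fold), ATG40 (8.56-fold) and ATG36 (25.7 ± 0.368 to 179.7 ± 5.37 FPKM). ATG10 (0.20) and ATG18 (-0.13) did not pass. Of 32 redox genes 21 rose and 9 fell, with a median of 0.66 (camera adjusted p = 0.0266; adjusted p = 0.381 with an estimated correlation), and the call was lost under 2 scalings (adjusted p = 0.196 after quantile normalization and 0.0619 after median centring). The glutaredoxin GRX2 and the glutathione transferase GTT1 rose 10.8-fold and 9.77-fold, the NADPH oxidoreductase OYE2 was 25.8-fold lower, and GLR1 and TSA1 (both -0.01) did not pass. Cell wall genes went both ways, 9 of 26 higher and 16 lower, or 10 and 16 adjusted over the list alone (median -0.56, camera adjusted p = 0.378), with TOS6 (-5.55 ± 0.097, SE) and NCW2 (-3.54 ± 0.087) lower and PIR3 (3.52 ± 0.051) higher. GSC2 (0.13) did not pass over all genes.

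Several lists of biosynthetic genes fell. In the list of arginine, lysine, histidine and branched-chain amino acid synthesis 29 of 35 members fell, with a median log2 fold change of -1.79 (camera adjusted p = 7.78e-05; adjusted p = 0.355 with an estimated correlation). BAT1, the mitochondrial branched-chain aminotransferase, was 13.8-fold lower and LEU9 17.7-fold lower, while the cytosolic form BAT2 rose 9.70-fold. The other members that rose were LEU4 (0.97), LYS5 (0.84), GCN4 (0.20) and ILV6 (0.17), and ARG8 did not pass (-0.15). Sulfur amino acid genes went both ways, 12 of 24 higher and 9 lower (median 0.17, camera adjusted p = 0.5), with CYS3 at -3.31 ± 0.080 (SE), MET28 at 2.64 ± 0.079 and MET6 at 2.55 ± 0.062. MET8 (-0.13), SUL1 (-0.01) and SUL2 (-0.14) did not pass. Of 12 fatty acid synthesis genes 10 fell, with a median of -1.14 (camera adjusted p = 0.0171; adjusted p = 0.426 with an estimated correlation), including the elongases ELO2 (22.8-fold lower) and ELO3 (17.3-fold lower) and the activating enzyme FAA4 (5.29-fold lower); SPT23 (0.59) and FAA1 (0.36) rose. Of 26 ergosterol genes 18 fell and 5 rose, with a median of -0.71 (camera adjusted p = 0.0473; adjusted p = 0.396 with an estimated correlation), and the call was lost without non-stress replicate 2 (adjusted p = 0.0513), without stress replicate 2 (0.0553) and after median centring (0.0715). ERG11, lanosterol demethylase, went from 163 ± 12.2 to 36.2 ± 1.60 FPKM, and the sterol regulator UPC2, ERG25 and ERG1 were 9.71-fold, 8.12-fold and 5.87-fold lower. HMG1 (1.06), ERG28 (1.05), ERG9 (0.96), HMG2 (0.86) and ERG10 (0.43) rose, and ERG8 (-0.11), ERG24 and ERG4 (both 0.01) did not pass.

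Genes of DNA replication and the G1/S cyclins fell, 22 of 28, with a median log2 fold change of -0.69 (camera adjusted p = 0.00709; adjusted p = 0.355 with an estimated correlation). POL30, the replication clamp, was 9.45-fold lower, the cyclin CLN2 5.24-fold and RFA2 2.28-fold, while MCM4 rose (0.35) and MCM7, PRI1, CLN1, CLB5 and SWI4 lay between -0.05 and 0.05 and did not pass. Histone genes went both ways, 3 of 10 higher and 3 lower, with a median of -0.01 that became 0.18 after median centring (camera adjusted p = 0.916). HTB2 (-1.43 ± 0.052, SE), HTA2 (-1.39 ± 0.075) and HTA1 (-0.63) fell, HTZ1 (0.64 ± 0.052), HHT1 (0.59) and HHO1 (0.45) rose, and HTB1 (0.09), HHT2 (0.01), HHF1 (-0.03) and HHF2 (-0.06) did not pass.

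Iron regulon genes rose in 16 of 25 cases and fell in 6, with a median log2 fold change of 0.53 (camera adjusted p = 0.0171; adjusted p = 0.426 with an estimated correlation). FIT2, a cell wall protein that retains siderophores, rose 119-fold (6.20 ± 0.955 to 738 ± 9.28 FPKM, SD, n = 2), and the siderophore transporters SIT1 and ARN2 14.5-fold and 8.37-fold. FIT1 (-0.07), FRE4 (-0.23) and MRS4 (-0.04) did not pass. Of 20 thiamine genes 4 were higher and 12 lower, or 3 and 12 adjusted over the list alone (median -0.65, camera adjusted p = 0.189). THI20 was 12.2-fold lower, and SNZ2 and SNZ3, which share 77.1% of their windows with each other, rose 21.6-fold and 22.3-fold. The other members that were higher, SNO3 (1.59) and THI11 (0.84), and 3 of the 4 that did not pass, THI5 (-0.06), THI12 (-0.20) and THI13 (-0.01), also share most windows with copies; the last was THI74 (0.16). Of 15 phosphate genes 3 were higher and 10 lower (median -0.19, camera adjusted p = 0.331), with PHO84 5.28-fold lower, VTC3 1.90-fold lower and PHO4 2.46-fold higher. PHO81 (0.24) and SPL2 (0.55) were the other members that rose, and PHO89 (-0.03) and PHM8 (0.09) did not pass. Of 29 hypoxia genes 15 were higher and 9 lower, or 14 and 9 adjusted over the list alone (median 0.32, mean -0.21, camera adjusted p = 0.437). Beside the falls of TIR1 and ANB1, CYC7, a second cytochrome c gene, rose 11.9-fold. COX5B (0.15), HEM14 (0.02), PDR11 (0.06), PAU10 (-0.50) and PAU12 (-0.14) did not pass.

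Lists included as checks of growth state and cell type gave the following. Of 17 genes known from stationary phase 14 rose, with a median log2 fold change of 1.79 (camera adjusted p = 0.000309; adjusted p = 0.355 with an estimated correlation), among them SPG4 (6.33 ± 2.91 to 620 ± 5.88 FPKM, SD, n = 2) and SPG1 (31.0 ± 4.87 to 1522 ± 12.6 FPKM). ADH2 and RIM15 (-0.49) fell, and PRM1 (0.21) did not pass. Haploid-specific and mating genes were low, and 0 of the 19 tested had a mean of 20 FPKM or more. Of them 4 were higher and 5 lower, with a median of -0.07 that changed sign after quantile normalization (0.47) and median centring (0.12; camera adjusted p = 0.875). Those that were higher were FUS3 (1.02), STE2 (0.81), RME1 (0.75) and STE4 (0.33), and those that were lower AGA2 (-2.10), BAR1 (-0.90), SST2 (-0.63), FUS1 and MF(ALPHA)2 (both -0.48). Of 23 meiosis genes 6 were higher and 14 lower (median -0.62, camera adjusted p = 0.377), and IME1 and IME4, regulators of entry into meiosis, rose 2.08-fold and 1.70-fold. IME2 (0.14), REC8 (-0.21) and SPO20 (0.11) did not pass.

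**Figure D3:**
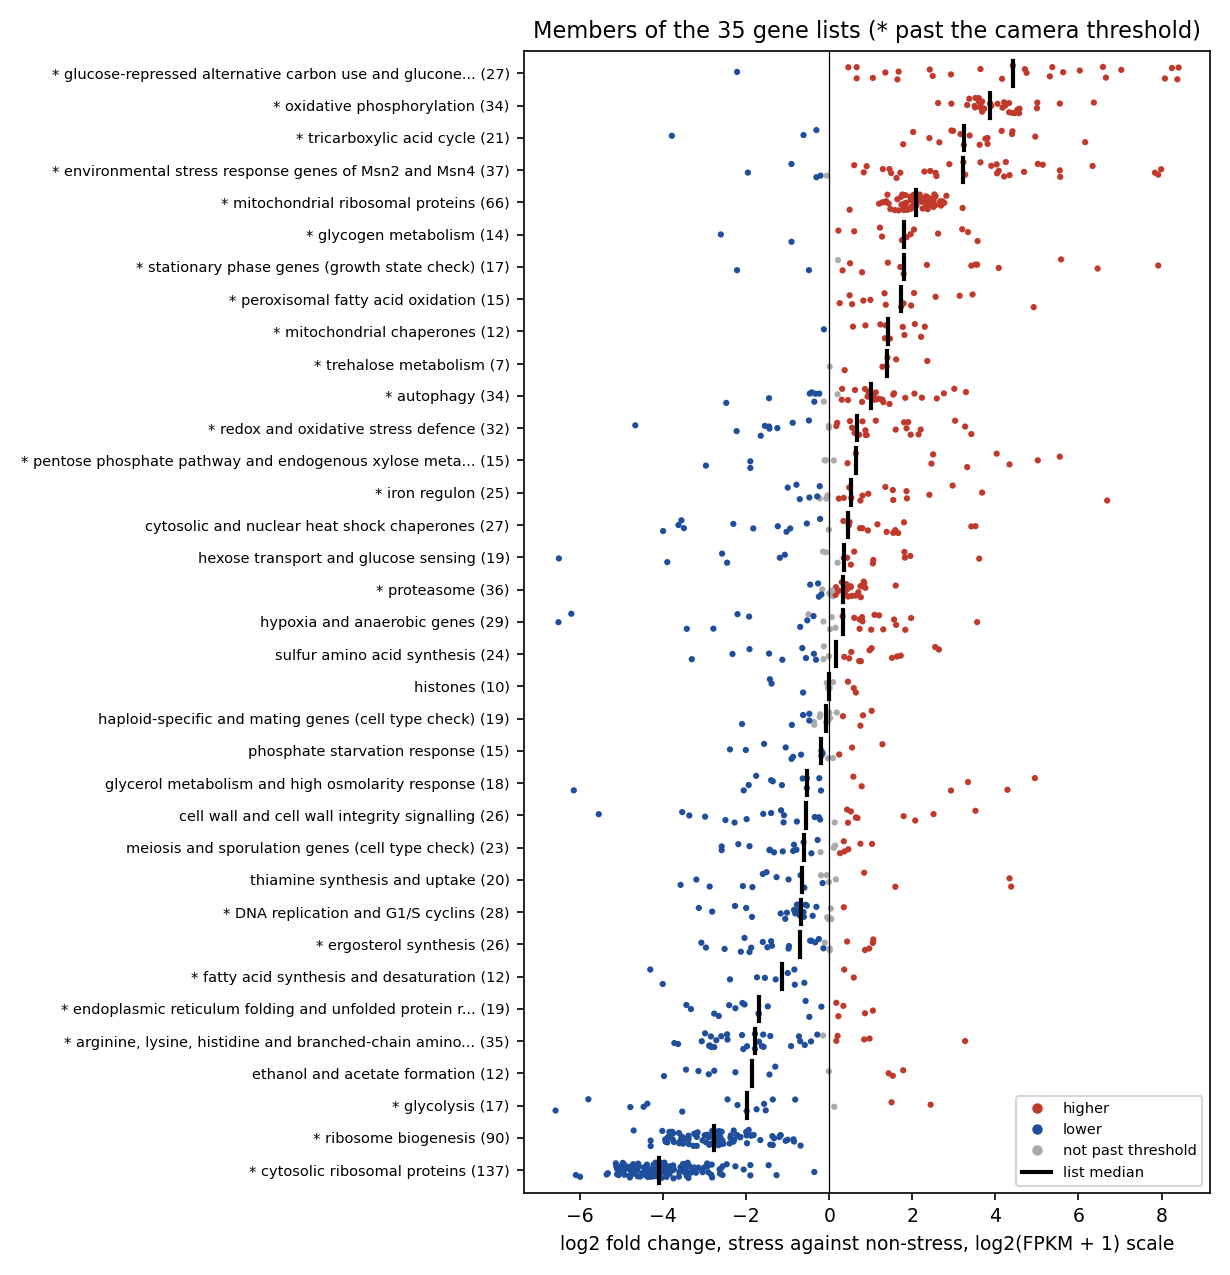
Log2 fold change (horizontal axis, stress against non-stress on the log2(FPKM + 1) scale) of each tested member of the 35 gene lists, ordered by list median. Red points were higher, blue points lower and grey points not past the limma threshold; black bars are medians, from -4.11 for cytosolic ribosomal proteins to 4.42 for glucose-repressed carbon use, and an asterisk marks the 23 lists past the camera threshold.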

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

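The count of changed genes, 5071, was 5073 after quantile normalization, 5076 without a filter, 4981 with a minimum FPKM of 5, 5062 with a pseudocount of 0.1 and 4758 at an adjusted p of 0.01. It ran from 4776 to 5052 when each library was left out in turn, where a lone library is assumed to vary like the other group. Alternatives chosen after seeing the data gave 5071 (rescaled to equal FPKM sums), 5105 (median centring) and 4968 (without genes with mostly shared windows). Labels do not say that replicate numbers mark a batch, and deviations of same-numbered libraries had a correlation of -0.005 across genes; with the replicate number as a block, 5073 genes changed, 5021 of them among the main calls. Scaling moved the balance of directions: the median log2 fold change of all genes, -0.14, became 0.09 after quantile normalization, 0.05 after median centring and -0.22 after rescaling to equal sums, with 46.9%, 47.9% and 57.8% of calls lower, against 54.6%. Quantile normalization reversed 23 calls. In a check chosen after seeing the data, ribosomal protein genes were taken out of the total, and the median of the remaining tested genes was -0.53. Changes no larger than these shifts therefore depend on the scaling. Small ones such as GRE3 (0.44) and the proteasome median (0.33) were not tested again on that total. The 117 named genes kept direction and call in all 1400 recomputed values. Apart from the genes named in any case, they were chosen from the same data for the largest changes, among all genes or within a list. For those chosen genes the stability was largely fixed by that choice, so it is no separate test of robustness. Of 35 lists 23 passed camera, and 20 to 23 passed under the other scalings, filters, pseudocount and block. With an estimated correlation 0 passed, and camera's adjusted p was 0.355 to 0.467 for those 23. The estimate lay below the preset 0.01 for some of them, as for oxidative phosphorylation (-0.025, adjusted p = 0.355), so a higher estimate is not what lost those calls. It lay far above 0.01 for cytosolic ribosomal proteins (0.527), trehalose (0.432), glycogen (0.417) and ribosome biogenesis (0.374). Their p-values at the preset therefore assume much less correlation than was estimated. The version of camera with an estimated correlation rests on 2 residual degrees of freedom, so it had little power to pass any list. The estimates themselves are uncertain for the same reason. With fry 33 lists passed, and 3 had a direction down in place of camera's up: cytosolic chaperones (median 0.46), hypoxia (0.32) and histones (-0.01). Their mean log2 fold changes were below 0 (-0.09, -0.21 and -0.18). Camera sets a list against all other genes, and the median of all genes was also below 0 (-0.14). Whether this is the whole cause was not tested. DESeq2 and both edgeR normalizations (RLE and library totals) were not run because the table holds no counts, and limma on FPKM was already the main test. In simulated data with 2 libraries in each group and 220 of 5784 genes changed, 76% of 1.5-fold changes were recovered. Far more genes changed here, which loosens the adjusted threshold, so that share need not hold for this comparison. Small changes can still be missed.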

Other observations

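All tests in this part were chosen after the results were seen, except the list of stationary phase genes, which was fixed before but set against this pattern afterwards. Of 1502 gene ontology terms with 15 to 80 tested members, 295 passed camera at its preset correlation, 138 up and 157 down, and 0 with an estimated correlation (adjusted p = 0.999 for the terms named here). None of the terms that passed had a median of the opposite sign under quantile normalization, rescaling to equal FPKM sums or median centring. Terms outside the ribosome fell too, of which some are given as examples. All 16 genes of the RNA polymerase III complex were lower (median log2 fold change -2.07, camera adjusted p = 0.00025), as were all 16 with tRNA methyltransferase activity (median -2.15, adjusted p = 0.000372). Of 37 translation initiation factor genes 30 were lower (median -1.59, adjusted p = 0.00117), and of 15 genes of the RNA exosome, which degrades and trims RNA, 12 (median -1.18, adjusted p = 0.0422). Of 47 nuclear pore genes 37 were lower (median -0.70, adjusted p = 0.0128), of 73 protein glycosylation genes 57 (median -0.89, adjusted p = 0.000234) and of 15 genes of the proton-pumping V-type ATPase 14 (median -0.70, adjusted p = 0.0183). Among higher terms, of 20 cristae formation genes 19 were higher (median 1.67, adjusted p = 1.83e-06), of 21 genes that assemble respiratory complex IV 20 (median 2.27, adjusted p = 5.36e-07) and of 24 genes that target proteins to the peroxisome 19 (median 0.64, adjusted p = 0.00162).

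Many duplicate genes split, with one copy higher and the other lower. Of 291 pairs in which both copies changed, 102 did so in opposite directions (35.1%), and none of these 102 lay in the cytosolic ribosome. Copies that share sequence can receive each other's reads, and some have identical values, which draws them to the same direction. The main comparison with random pairings was therefore limited to 182 pairs outside the cytosolic ribosome. In these pairs neither copy shared a 50-base window with another gene. Of these 92 were opposite (50.5%), against 50.1% in random pairings (two-sided permutation p = 1, 100000 resamples). Among these 182 pairs alone, no tendency of copies to move together or apart was detected. Of the 53 pairs outside the cytosolic ribosome with shared windows 10 were opposite (18.9%), against 49.6% in random pairings (two-sided permutation p = 1e-05). Copies with identical values, such as COS2 and COS3, cannot be opposite. That low share was therefore partly fixed in advance, and nothing about regulation of the copies is drawn from it. The share among pairs without shared windows was 49.2% after quantile normalization, 48% after rescaling to equal FPKM sums and 52.2% after median centring. Among examples chosen after their values were seen, the mitochondrial carriers ODC1 and ODC2 had log2 fold changes of 4.96 and -3.79, and the glutamate dehydrogenases GDH3 and GDH1 4.83 and -3.83. In the pentose phosphate pathway, GND2 and TKL2 were higher (5.55 and 4.34) and the main copies GND1 and TKL1 lower (-1.90 and -2.97). Malate synthase MLS1 was higher (7.03) and its copy DAL7 lower (-3.12), and FHN1 and NCE102, of the plasma membrane, were at -3.55 and 3.17. What sets the copies apart was not tested.

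Genes that glucose represses were higher, and glycolytic genes, HXT1 and HXT3 lower, in the libraries labelled with more glucose, opposite to the label. The fall of ribosomal protein transcripts leaves a smaller total, but that shift is too small for this rise. Those genes held 23.1% of the summed FPKM in non-stress and 1.55% in stress libraries. The glucose-repressed list had a median log2 fold change of 4.42. With ribosomal protein genes taken out of the total it was 3.99 (median absolute deviation 2.29, 27 genes), while that of all genes was -0.53. Those shares fixed in advance that the median would stay high, so this gives the size of the shift and is no separate test. An exchange of the labels of all 4 libraries cannot be told apart from the stated labels, because 19 chaperone genes regarded as targets of the heat shock factor Hsf1, listed to test it, had a median of 0.47 with members going both ways (11 higher, 7 lower, median absolute deviation 1.19). A candidate explanation is that the cultures labelled stress were past growth on glucose at harvest. Set against it, those cultures were given 10% glucose against 2% and were harvested at the same 10 h. The 16 stationary phase genes outside the glucose-repressed list had a median of 2.07 (14 higher, 1 lower). The member left out was ADH2, which fell (-2.22), and with it the median was 1.79 (14 higher, 2 lower). The 16 include 3 genes of the Msn2 and Msn4 list and 2 heat shock chaperones, which stress alone could raise. The test therefore cannot tell that growth state from a stress response. That test would come out the same way with exchanged labels if the other cultures had used up their glucose, and no glucose or cell density reading was used here, so both stay open beside a direct effect of heat.

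ADH2 was lower while the other 26 genes of its list rose. A fixed share of ADH1 reads counted for ADH2 could make it follow ADH1, but ADH2 was 28.4% ± 0.49 of the FPKM of ADH1 in non-stress and 41.3% ± 0.38 in stress libraries (SD, n = 2), which argues against a fixed share as the whole cause. A part from ADH1 reads, and a difference of strain CY from the reference at either gene, were not tested. A biological difference in how ADH2 answers to heat or glucose also stays open, as untested.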
